A study of Mus musculus with 9 samples.

How the data were processed

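RNA was measured in 9 libraries of mouse prostate basal cells that had been flow-sorted from C57BL/6J animals and grown as organoids for 5 days. The media define the 3 groups of 3 libraries each, and groups were taken from the sample titles and treatment labels. BM is the basal organoid medium, which holds EGF, Noggin (a BMP antagonist), an inhibitor of the TGF-β type I receptor and a ROCK inhibitor. R is BM with R-spondin1 at 500 ng/ml, a secreted protein that raises the response to Wnt ligands. RD7 is R with dihydrotestosterone (DHT) at 100 nM, the potent androgen. No group had DHT without R-spondin1, so the effect of DHT alone and the dependence of either factor on the other were not tested. Polyadenylated RNA was amplified as full-length cDNA with a SMART-Seq kit, which does not mark the strand of a transcript, and carried no molecular identifiers.

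The deposited values are FPKM, reads scaled by gene length and by the total reads counted in the library, 1 value for each of 49585 genes in each library. Per the labels, the authors' processing notes name CASAVA 1.9, STAR 2.6.1a, featureCounts, edgeR 3.24.1 and the mouse build GRCm38, without the role of each, the annotation release, the strand setting or any filter. A symbol in GENCODE M21 (GRCm38) was found by gene identifier for 99.5% of genes, and 259 identifiers were not in that release. Reads per gene were read back by multiplying FPKM by gene length and by the library's smallest step. With the merged exon length of GENCODE M21, the product was a whole number within 0.01 of a read for 22971 of the 26813 genes above 0 in any library. A length was fitted for the other 3842, and at least 99.988% of each library's reads were read back. The reads counted came to 6505859, 24141017 and 19606757 in BM 1 to 3, to 15961444, 23256008 and 21657601 in R 1 to 3, and to 17893595, 19102843 and 16894535 in RD7 1 to 3. A gene with 0 reads in a library could stand at up to 0.461 CPM (reads scaled by the total of the library) in BM 1 and at up to 0.188 in the other libraries (3 reads). Such floors, and the intervals of ratios given for genes with few reads, cover counting error only, because amplified reads without identifiers are not independent molecules. Genes with 0 in all libraries numbered 22772.

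A count-based test had been planned. Because the values are FPKM, log2(FPKM + 0.5) was tested instead with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 libraries, 6 residual degrees of freedom, and an empirical Bayes step with a trend and robust settings. Genes with at least 0.5 CPM in at least 3 libraries were tested, 15867 in all. The comparisons were R against BM, RD7 against R, and RD7 against BM, the last being the sum of the others. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which shrinks those of genes near or below 0.5 FPKM. The labels do not state whether the 3 libraries of a group came from separate animals or sorts, so every p-value measures the spread between samples whose separate origin is not stated. On simulated data made from the same libraries, the test found 36.7% of 2-fold and 85.9% of 4-fold changes for R against BM. For RD7 against R it found 35.4% and 82.8%, for RD7 against BM 44.0% and 89.8%, and between 4.72% and 5.04% of calls were false. The simulation drew each gene independently, without differences between libraries that many genes share, so these shares may not hold for the real data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading, tables and plots.

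The following were fixed before the data were examined: the comparisons, the threshold, 22 gene lists, the genes to name and the first set of other settings. The lists hold Wnt/β-catenin target genes, Wnt ligands, receptors and secretion genes, androgen-response genes, markers of basal, luminal and proximal (urethral) luminal progenitor cells, prostate secretory protein genes, and squamous differentiation genes. Others hold genes of mitosis, DNA replication, sterol synthesis, fatty acid synthesis, the Notch pathway, the BMP and TGF-β response, glycolysis and hypoxia, the interferon response, and the immediate-early and heat-shock response. The last 5 hold markers of mesenchymal, immune, endothelial and neuroendocrine cells and of the seminal vesicle. Not every member of the secretory list encodes a secreted protein, as Mme encodes a membrane peptidase. Lists with at least 5 members tested, 18 in all, were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The named genes were a fixed set (among them Axin2, Lgr5, Notum, Nkd1, Fkbp5, Krt5, Krt14, Trp63, Krt8, Krt18 and Mki67), the 6 called genes with the highest and the 6 with the lowest log2 fold change, and up to 4 called members of each called list. The highest and lowest genes needed a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Predicted gene models were left out. For RD7 against BM, 4 and 4 were taken, and list members already named in the other comparisons. Members named because a count is 5 or smaller, and the families described in the closing section, were chosen after their values were seen.

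Other settings fixed beforehand were median-of-ratios scaling, no filter on low values, a filter of 1 CPM in 3 libraries, a fit of the 6 libraries compared, the replicate number as a block, a minimum fold of 2, and leaving out each library in turn. Pseudocounts of 0.1 and 1, limma-voom on the reads read back, and removal of each library's trend with gene length by loess were added after the data had been seen. Genes called in both the R-spondin1 and DHT steps were counted by direction, against the product of the list sizes and against 50 simulations of unchanged groups. Of 136 genes named by the rule or grouped in families, 37 share exon bases with another annotated gene, 13 of them on at least 10% of their exon bases. Reads of the other gene may be counted in these, as the strand was not marked. No value column or library was left out.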

Results

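Gene expression was measured by RNA sequencing in 9 libraries of mouse prostate basal cells cultured as organoids for 5 days, with 3 libraries in BM medium, 3 in BM with R-spondin1 (R) and 3 in R with DHT (RD7). The series asks how Wnt and androgen signaling change these organoids. Depth ranged from 6505859 reads counted in BM 1 to 24141017 in BM 2. Values are mean FPKM ± SD with n = 3 libraries in each group, fold is the ratio of mean FPKM, and log2 fold changes (± SE) are on the log2(FPKM + 0.5) scale. For every gene called by limma and named below in R against BM or RD7 against R, each library of 1 group lay above each library of the other. Coordinates are on GRCm38.

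The 3 groups separated from each other. On the principal component that held 60.8% of the variance, the RD7 libraries lay between -76.7 and -48.9, the R libraries between 14.5 and 30.1 and the BM libraries between 18.8 and 55.9. The component that held 20.6% parted R, at 27.3 to 39.7, from BM, at -35.7 to -12.3. Pearson correlations between libraries across genes, which are not independent replicates, were 0.990 to 0.992 within R, 0.982 to 0.988 within RD7 and 0.969 to 0.979 within BM. Between groups they were 0.947 to 0.974 for BM and R, 0.914 to 0.946 for R and RD7 and 0.872 to 0.950 for BM and RD7. BM 3 lay nearer to R than BM 1 and BM 2 did. It correlated with R 1 at 0.97426, as closely as with BM 1 (0.97415) and more closely than with BM 2 (0.96919). Shorter genes were higher in R than in BM, with a Spearman correlation of -0.33 between log2 fold change and gene length across genes, and higher in RD7 than in R, with -0.22. The same correlation was -0.45 for BM 3 minus the other BM libraries and -0.38 for RD7 2 minus the other RD7 libraries. Ribosomal-protein genes, which are short, held 0.855% ± 0.325 of reads in BM, 1.03% ± 0.193 in R and 1.64% ± 0.189 in RD7.

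**Figure D1:**
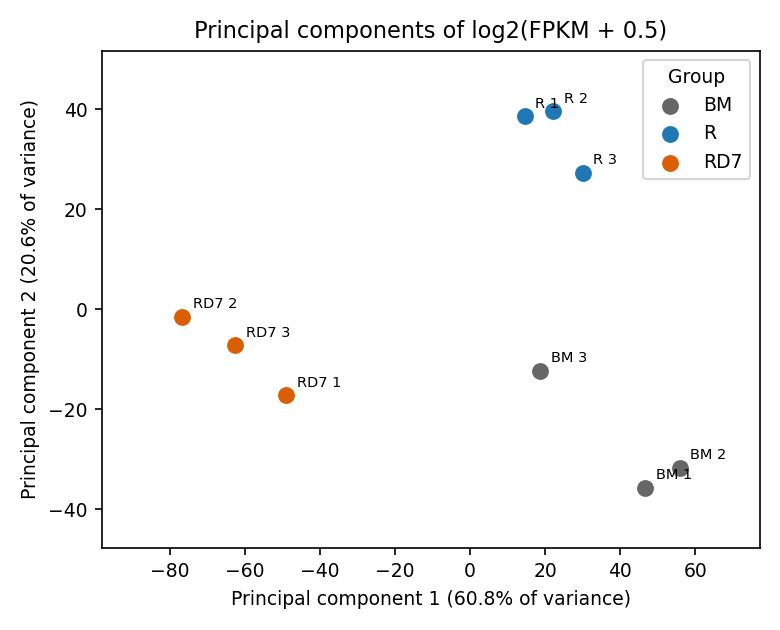
Position of each of the 9 libraries on the first principal components of log2(FPKM + 0.5), in units of the component scores, with colours for the medium. The RD7 libraries lie at -48.9 or below on the horizontal axis, and the R libraries lie at 27.3 or above on the vertical axis, where BM 3 lies at -12.3.

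R-spondin1 was compared with BM to ask which genes answer to stronger Wnt signaling. Axin2 (chromosome 11, 108920349 to 108950783), a feedback inhibitor of Wnt signaling, rose 12.2-fold from 0.351 ± 0.0381 to 4.28 ± 1.17 FPKM (log2 fold change 2.46 ± 0.19, limma adjusted p = 1.8e-05). Wif1 (chromosome 10, 121033960 to 121100650), which encodes a secreted Wnt inhibitor, rose 16.7-fold from 6.24 ± 0.661 to 104 ± 6.83 FPKM (3.96 ± 0.13, limma adjusted p = 2.3e-07). Lgr5 (chromosome 10, 115450311 to 115587780), an R-spondin receptor, rose from 0.00934 ± 0.00512 FPKM, 4 reads over the BM libraries, to 0.894 ± 0.157 FPKM (1.45 ± 0.11, limma adjusted p = 1.3e-05). Notum, a secreted enzyme that inactivates Wnt ligands, rose from 0.184 ± 0.108 to 1.67 ± 0.458 FPKM, and Nkd1 rose from 0.0820 ± 0.0322 to 0.375 ± 0.123 FPKM with a limma adjusted p of 0.012, which was 0.051 with limma-voom. Notum shares 29.4% of its exon bases with an antisense gene. Of 22 Wnt target genes tested, 10 rose, 1 fell and 11 were not called, and 10 and 2 were called when adjusted over the list alone. The gene that fell was Sp5, from 7.21 ± 0.889 to 2.72 ± 0.325 FPKM. The list rose with a median log2 fold change of 0.37 (camera adjusted p = 2.8e-04, and adjusted p = 0.220 with an estimated correlation).

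Squamous differentiation genes rose together with R-spondin1. Krt10, a keratin of differentiating squamous epithelium, rose 26.2-fold from 1.93 ± 0.480 to 50.4 ± 4.13 FPKM (log2 fold change 4.41 ± 0.23, limma adjusted p = 1.6e-06). Sprr2d, a precursor of the cornified envelope, rose from 1.28 ± 0.656 to 52.5 ± 14.5 FPKM, Cdsn, which encodes corneodesmosin, from 0.536 ± 0.187 to 7.66 ± 1.07 FPKM, and Krt6b from 1.69 ± 0.334 to 21.7 ± 1.83 FPKM. Of 23 genes tested on this list, 21 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.82. Camera gave an adjusted p of 6.9e-24, and an adjusted p of 0.059 with an estimated correlation. Calm4 (5.04 ± 0.22), Sprr2d (4.94 ± 0.30), Krt10, Sprr2f (4.15 ± 0.27), Wif1 and Cnfn (3.92 ± 0.45) had the 6 highest log2 fold changes under the naming rule. Reads of the close paralogs Sprr2d and Sprr2f, and of Krt6b, cannot be assigned with certainty.

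The genes that fell furthest with R-spondin1 under the naming rule were Upk3a, Gsdmc3, Adh1, Sult1c2, Gsdmc2 and Timp3. Upk3a (chromosome 15, 85017141 to 85022547), a membrane protein of the urothelial plaque, fell from 92.9 ± 26.7 to 1.57 ± 0.294 FPKM (log2 fold change -5.47 ± 0.23, limma adjusted p = 4.9e-07). Adh1, an alcohol and retinol dehydrogenase, fell from 37.6 ± 8.79 to 1.38 ± 0.112 FPKM. The gasdermin genes Gsdmc3 and Gsdmc2, close paralogs, fell from 96.4 ± 16.9 to 3.22 ± 0.176 and from 113 ± 6.99 to 7.42 ± 0.361 FPKM. Sult1c2, a sulfotransferase gene, fell from 12.0 ± 3.59 to 0.212 ± 0.150 FPKM. Timp3, a metalloproteinase inhibitor that shares 21.3% of its exon bases with Syn3, fell from 28.7 ± 6.05 to 1.83 ± 0.266 FPKM.

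Luminal and androgen-response genes included members that fell with R-spondin1. Prom1, a luminal progenitor marker, fell from 61.2 ± 6.50 to 12.3 ± 1.16 FPKM, Cd38 from 4.38 ± 0.141 to 0.740 ± 0.0279 and Dpp4 from 2.10 ± 0.242 to 0.648 ± 0.144. Krt8, a luminal keratin, fell from 1173 ± 99.5 to 652 ± 41.6 FPKM (log2 fold change -0.85 ± 0.14, limma adjusted p = 0.0027). Of 20 luminal genes, none rose, 7 fell and 13 were not called (1 and 7 adjusted over the list alone), with a median log2 fold change of -0.03. Camera gave an adjusted p of 0.032, and an adjusted p of 0.322 with an estimated correlation, 0.141 without BM 3 and 0.085 without R 3, in a range of 7.3e-04 to 0.322 over the settings. Of 36 androgen-response genes, none rose and 5 fell (2 and 8 adjusted over the list alone), with a median of -0.16. These were Hpgd (9.14 ± 0.514 to 2.21 ± 0.227 FPKM), Inpp4b (2.02 ± 0.439 to 0.257 ± 0.0224), Slc45a3 (30.4 ± 5.51 to 9.46 ± 0.360), Spdef (5.59 ± 1.29 to 1.95 ± 0.438) and Homer2 (4.94 ± 0.635 to 2.76 ± 0.362). Homer2 was not called without R 1 or R 3 or with the length trend removed (limma adjusted p up to 0.137). For the list, camera gave an adjusted p of 0.012, and an adjusted p of 0.243 with an estimated correlation and 0.061 with the length trend removed, in a range of 0.0027 to 0.243. The androgen-response gene Fkbp5 (5.84 ± 1.22 and 4.29 ± 0.737 FPKM) was not called.

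Among basal genes, Aqp3, a water and glycerol channel, rose 4.71-fold from 30.4 ± 5.92 to 143 ± 7.57 FPKM, and Dlk2 rose from 4.55 ± 0.719 to 8.82 ± 0.0735 FPKM. Krt15 (3094 ± 184 and 4543 ± 205 FPKM) and Snai2 (56.0 ± 9.33 and 83.1 ± 9.42) also rose, but their calls did not hold in every fit. Krt15 was not called without BM 2, R 1 or R 2 (limma adjusted p of 0.068, 0.094 and 0.091) or with the length trend removed (0.085). Snai2 was not called without BM 1, BM 2, R 1, R 2, RD7 2 or RD7 3, with a limma adjusted p of up to 0.169. These were the 4 of 20 basal genes that rose, and none fell (5 and 3 adjusted over the list alone). The basal list was not called (camera adjusted p = 0.942), and its median (-0.09), mean (0.00) and test (lower) differed in sign. Krt5 stood at 2600.5 ± 305 FPKM in BM and 3484 ± 58.9 in R (limma adjusted p = 0.055), Krt14 at 1751 ± 127 and 1921 ± 143, Trp63 at 40.7 ± 10.1 and 44.3 ± 8.63, the luminal keratin Krt18 at 963 ± 174 and 934 ± 97.6 and the proliferation marker Mki67 at 16.2 ± 5.29 and 11.1 ± 0.581, and none of these was called.

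Interferon-stimulated genes rose with R-spondin1. Ifit3 rose from 1.68 ± 0.385 to 7.39 ± 0.894 FPKM, the chemokine gene Cxcl10 from 2.35 ± 0.763 to 7.66 ± 1.27, Rsad2 from 0.670 ± 0.196 to 2.59 ± 0.111 and Irf7 from 11.2 ± 0.306 to 19.2 ± 0.127. Of 18 members, 6 rose and none fell (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.44 (camera adjusted p = 2.0e-04, and adjusted p = 0.147 with an estimated correlation). Of 4 leukocyte markers tested, Lyz2 (listed at 0 in BM and at 0.648 ± 0.00709 FPKM in R) and Cd68 (1.21 ± 0.364 and 2.64 ± 0.434) also rose, and Cd68 was not called without BM 1, BM 2, R 1, R 2 or R 3 (limma adjusted p up to 0.132). The glycolysis and hypoxia list rose (median 0.35, camera adjusted p = 0.0011, and adjusted p = 0.104 with an estimated correlation), with 3 of 20 members higher and none lower (10 and 0 adjusted over the list alone). These were Ankrd37 (6.67 ± 2.06 to 13.3 ± 1.20 FPKM), P4ha1 (22.3 ± 1.60 to 31.6 ± 0.769) and Egln3 (114 ± 7.78 to 157 ± 6.69). Ankrd37 was not called without R 1 (limma adjusted p = 0.059), P4ha1 without BM 2, R 1, R 2 or R 3 (up to 0.105), and Egln3 without BM 1, BM 2, R 1, R 2 or R 3 (up to 0.156).

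The Notch and fatty acid synthesis lists fell with R-spondin1. Of 14 Notch pathway genes, 3 fell and none rose (3 and 0 adjusted over the list alone), with a median log2 fold change of -0.29 (camera adjusted p = 0.0066, and adjusted p = 0.322 with an estimated correlation). Hey1, a transcription factor induced by Notch, fell from 26.7 ± 2.22 to 14.7 ± 1.03 FPKM. Maml2 (4.23 ± 0.741 to 1.84 ± 0.563 FPKM) was not called without BM 1, R 1 or R 2 (limma adjusted p of 0.051, 0.060 and 0.061). Heyl (0.383 ± 0.0647 to 0.128 ± 0.0429) was not called without R 1 (0.061) or with limma-voom (0.064). Of 16 fatty acid synthesis genes, Me1 (33.6 ± 5.77 to 20.9 ± 1.28 FPKM) and Dgat2 (15.5 ± 2.62 to 10.0 ± 0.575) fell and none rose (4 fell adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.0052, and adjusted p = 0.243 with an estimated correlation). Me1 was not called without BM 2, R 1, R 2 or R 3 (limma adjusted p up to 0.094), and Dgat2 without any 1 of BM 1, BM 2, R 1, R 2 and R 3 (up to 0.133).

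In all, limma called 1591 of 15867 genes between R and BM, 696 higher and 895 lower. Groups did not overlap for 30.3% of genes, where chance gives 10% for a gene taken alone. Many genes share differences between libraries, so the share in a single grouping can lie far from 10% without an effect of the medium. The counts rested on single libraries. Without BM 3, 2089 were higher and 1313 lower, so that 61.4% of calls were higher instead of 43.7%. The number higher was 458 without BM 1, 368 without R 1 and 381 without R 2, and the number lower was 562 without R 1 and 559 without R 2. The other lists were not called. Their camera adjusted p was 0.138 for sterol synthesis (Cyp51 fell, of 20), 0.185 for immediate-early and heat-shock genes (Ier3 rose and Egr2 fell, of 18), 0.193 for DNA replication and 0.258 for Wnt ligands and receptors (Wnt3a and Fzd10 rose and Wnt7a, Fzd4 and Wnt7b fell, of 29). It was 0.258 for mesenchymal markers (Dcn rose and Vim, Acta2 and Tagln fell, of 10), 0.289 for secretory genes (Gsdma and Spink5 rose, of 10) and 0.469 for proximal markers (5 rose, among them Psca, Lypd3, Ly6d and Ly6a, and Cyp2f2, Trpv6, Ppp1r1b, Clu and Krt7 fell, of 16). It was 0.469 for the BMP and TGF-β response (Bmp7, Tgfbi and Id4 rose and Ccn2 and Atoh8 fell, of 16) and 0.708 for mitosis. Limma and limma-voom called 0 of 21 replication genes and 0 of 21 mitotic genes, and 2 and 0 of them had an unadjusted p under 0.05. With fry, replication had an adjusted p of 0.033 and mitosis 0.563. The calls of Ier3, Tagln, Wnt7b, Bmp7, Id4, Tgfbi, Ly6d, Ly6a and Krt7 were each lost without R 1 and without R 2, and at least 1 of them without each of the other 7 libraries (limma adjusted p up to 0.197). The proximal list's median (0.05) and mean (-0.09) differed in sign.

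DHT was added on top of R-spondin1 in RD7, and RD7 against R asks which genes answer to androgen in the presence of R-spondin1. The androgen-response gene Fkbp5 (chromosome 17, 28399094 to 28517527), a chaperone of steroid receptors, rose 25.5-fold from 4.29 ± 0.737 to 109 ± 16.3 FPKM (log2 fold change 4.52 ± 0.18, limma adjusted p = 9.2e-08). Mme, a membrane metalloendopeptidase gene, rose from 0.0233 ± 0.0181 to 6.47 ± 0.708 FPKM. Zbtb16, a zinc finger transcription factor gene, rose from 1 read over the R libraries to 5.25 ± 1.01 FPKM, with a 95% counting interval of the ratio of 303 to 66719. Of 36 androgen-response genes, 20 rose, 7 fell and 9 were not called (20 and 10 adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 5.8e-06, and adjusted p = 0.067 with an estimated correlation).

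Prostate secretory and luminal genes rose with DHT. Sbp (chromosome 17, 23941672 to 23945607), which encodes a spermine-binding prostate secretory protein, rose from 0.132 ± 0.0710 to 174 ± 15.1 FPKM (log2 fold change 8.11 ± 0.15, limma adjusted p = 5.0e-10). Spink5, a serine protease inhibitor gene, rose from 6.23 ± 0.478 to 72.8 ± 14.5 FPKM. Apof was listed at 0 in all 3 R libraries and stood at 6.04 ± 1.65 FPKM in RD7, at least 236.5-fold higher than 3 reads over the R group. Of 10 genes tested on the secretory list, 7 rose and 1, Gsdma, fell (7 and 1 adjusted over the list alone). Their median was 3.55, or 3.58 with the members at 0 set to their bound. Camera gave an adjusted p of 7.7e-07, and an adjusted p of 0.040 with an estimated correlation. Among luminal genes, Spdef, a transcription factor gene, rose from 1.95 ± 0.438 to 16.7 ± 0.717 FPKM, the prostate homeobox gene Hoxb13 from 43.0 ± 4.50 to 246 ± 41.0 and Prom1 from 12.3 ± 1.16 to 47.8 ± 9.90. Of 20 luminal genes, 10 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 1.1e-04, and adjusted p = 0.107 with an estimated correlation). Those that fell were Gata3, Cd24a and Krt18. Krt18 stood at 934 ± 97.6 FPKM in R and 653 ± 101 in RD7 with a limma adjusted p of 0.041, which was 0.10 with median-of-ratios scaling and up to 0.135 without BM 1, R 1, R 2, R 3, RD7 1 or RD7 3. Krt8 (652 ± 41.6 and 817 ± 108) was not called (limma adjusted p = 0.10).

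Markers of proximal luminal progenitors also rose with DHT. Cyp2f2, a cytochrome P450 gene, rose 11.7-fold from 27.4 ± 2.85 to 321 ± 30.8 FPKM, Ppp1r1b from 26.0 ± 3.50 to 130 ± 17.2, Krt7 from 99.4 ± 8.49 to 263 ± 40.3 and the calcium channel gene Trpv6 from 0.382 ± 0.0192 to 1.66 ± 0.140. Of 16 genes, 7 rose and 4 fell, Ltf, Clu, Lypd3 and Sox2 (8 and 4 adjusted over the list alone), where Sox2 was not called without R 1, R 2, R 3 or RD7 2 or with median-of-ratios scaling (limma adjusted p up to 0.099). The list rose with a median log2 fold change of 0.65 (camera adjusted p = 0.011, and adjusted p = 0.323 with an estimated correlation). The genes with the highest log2 fold changes under the naming rule included Sbp, Lrg1 (6.47 ± 0.17), Cldn10 (6.37 ± 0.27), Chad (6.35 ± 0.16) and Abo (6.27 ± 0.15). Lrg1, a secreted glycoprotein gene, rose from 2.41 ± 0.326 to 259 ± 47.2 FPKM, the tight-junction gene Cldn10 from 0.943 ± 0.296 to 117 ± 13.0, the matrix protein gene Chad from 0.0708 ± 0.0614 to 46.4 ± 7.94, and the glycosyltransferase gene Abo from 0.0321 ± 0.0555, 4 reads, to 40.6 ± 5.30.

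Basal genes fell with DHT. Krt5 fell from 3484 ± 58.9 to 2397 ± 91.9 FPKM (log2 fold change -0.54 ± 0.12, limma adjusted p = 0.0086), Krt17 from 657 ± 56.7 to 330 ± 38.2, Aqp3 from 143 ± 7.57 to 54.8 ± 3.93, the integrin gene Itga3 from 109 ± 9.96 to 60.7 ± 8.63 and Ngfr from 6.09 ± 0.858 to 2.66 ± 0.0869. Of 20 basal genes, 12 fell and 1, Dlk2, rose (14 and 1 adjusted over the list alone), a call lost without BM 1, R 1, R 2, R 3, RD7 1 or RD7 2 (limma adjusted p up to 0.165). The list fell with a median of -0.79 (camera adjusted p = 7.1e-04, and adjusted p = 0.117 with an estimated correlation). Trp63, the basal transcription factor p63, fell from 44.3 ± 8.63 to 26.5 ± 6.06 FPKM with a limma adjusted p of 0.030, and was not called without R 2, R 3, RD7 2 or RD7 3 (0.055, 0.115, 0.109 and 0.096). Krt14 (1921 ± 143 and 1754 ± 146) was not called. Squamous genes fell as well, with Ivl, a cornified envelope precursor, falling from 165 ± 10.2 to 27.0 ± 5.02 FPKM, Krt6b from 21.7 ± 1.83 to 3.05 ± 0.132, Cdsn from 7.66 ± 1.07 to 0.842 ± 0.0942 and Krt16 from 108 ± 7.50 to 31.5 ± 3.22. Of 23 squamous genes, 17 fell and 1, Krtdap, rose (19 and 1 adjusted over the list alone), a call lost without R 2, R 3, RD7 1, RD7 2 or RD7 3 (limma adjusted p up to 0.133). The list fell with a median of -1.15 (camera adjusted p = 2.6e-07, and adjusted p = 0.108 with an estimated correlation).

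Wnt target genes went both ways with DHT. Lgr5 fell from 0.894 ± 0.157 to 0.0132 ± 0.0146 FPKM (log2 fold change -1.44 ± 0.11, limma adjusted p = 4.5e-06), Notum from 1.67 ± 0.458 to 0.143 ± 0.0818, Nkd1 from 0.375 ± 0.123 to 0.0401 ± 0.0432 and Apcdd1, a Wnt inhibitor gene, from 22.6 ± 0.861 to 3.54 ± 1.56. Axin2 stood at 4.28 ± 1.17 FPKM in R and 3.97 ± 0.595 in RD7 and was not called (-0.08 ± 0.19, limma adjusted p = 0.793). Of 22 Wnt targets, 14 fell, 5 were not called and 3 rose, Sp5, Lef1 and Bambi (16 lower and 3 higher adjusted over the list alone). Sp5, a transcription factor gene, rose from 2.72 ± 0.325 to 8.60 ± 1.13 FPKM. The list fell with a median of -0.60 (camera adjusted p = 0.0025, and adjusted p = 0.193 with an estimated correlation). Among Wnt ligands and receptors, Wnt5a fell from 5.42 ± 0.398 to 0.392 ± 0.10 FPKM, Fzd10 from 4.31 ± 1.22 to 0.911 ± 0.322, Wnt3a from 1.20 ± 0.113 to 0.148 ± 0.189 and Sfrp1, a secreted inhibitor gene, from 1.20 ± 0.0801 to 0.155 ± 0.0742. Of 29 genes, 12 fell and 2, Fzd9 and Wnt9a, rose (12 and 3 adjusted over the list alone), with a median of -0.32. Wnt9a was not called without R 1, R 2, R 3, RD7 1 or RD7 3 (limma adjusted p up to 0.067). Camera gave an adjusted p of 0.025, and an adjusted p of 0.320 with an estimated correlation and 0.0504 with the length trend removed, in a range of 9.1e-04 to 0.320.

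**Figure D2:**
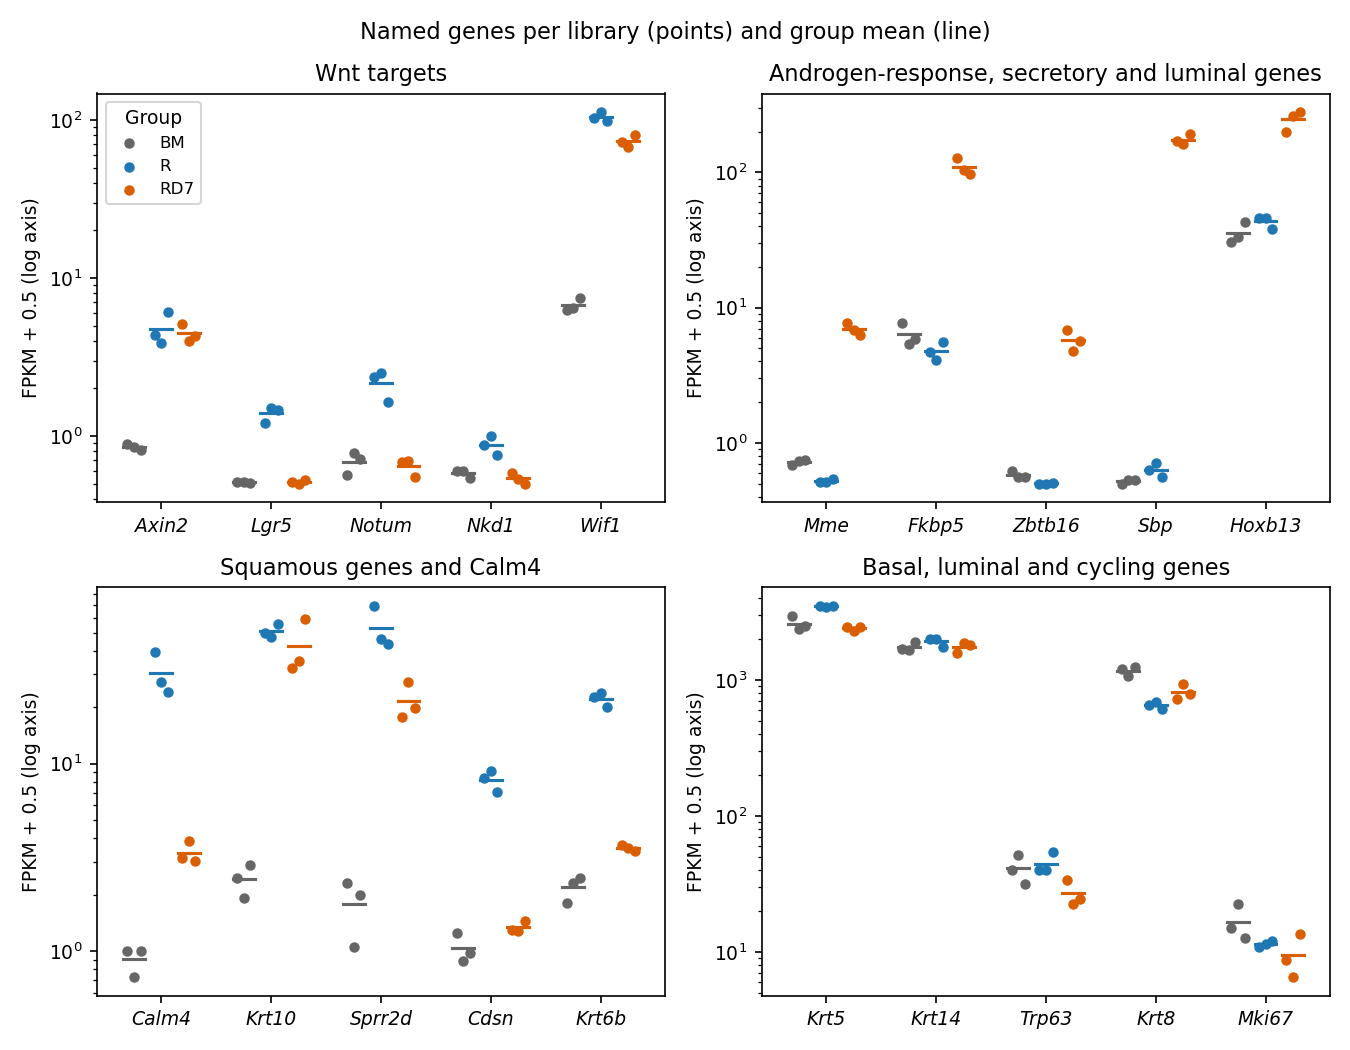
FPKM + 0.5 on a log axis for 20 named genes in 4 panels, with a point for each library, a line at each group mean and n = 3 libraries for BM, R and RD7. Axin2 stood at 0.351, 4.28 and 3.97 FPKM in BM, R and RD7, and Lgr5 at 0.00934, 0.894 and 0.0132.

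Genes of DNA replication and mitosis fell with DHT. The helicase subunit genes Mcm4 and Mcm3 fell from 85.7 ± 7.15 to 37.8 ± 6.80 and from 72.2 ± 3.31 to 37.1 ± 1.67 FPKM, Mcm5 from 85.0 ± 2.33 to 45.6 ± 4.01 and Cdt1 from 27.7 ± 1.26 to 15.7 ± 1.45. Of 21 replication genes, 14 fell and none rose (14 and 0 adjusted over the list alone), with a median log2 fold change of -0.69 (camera adjusted p = 2.4e-06, and adjusted p = 0.040 with an estimated correlation). Tpx2 fell from 32.3 ± 1.54 to 17.8 ± 1.18 FPKM, Top2a from 29.4 ± 2.10 to 17.4 ± 1.70, Kif20a from 43.6 ± 1.96 to 25.4 ± 3.11 and Plk1 from 91.4 ± 3.56 to 60.4 ± 6.02. Of 21 mitotic genes, 12 fell and none rose (15 and 0 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 7.8e-05, and adjusted p = 0.107 with an estimated correlation). Mki67, at 11.1 ± 0.581 FPKM in R and 9.08 ± 3.54 in RD7, was not called. Secretory and replication genes were the lists whose calls held with an estimated correlation in any comparison.

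Glycolysis and hypoxia genes fell with DHT, and interferon-stimulated genes rose. Car9, a carbonic anhydrase gene induced by hypoxia, fell from 80.3 ± 3.82 to 14.1 ± 2.62 FPKM, Vegfa from 46.2 ± 3.25 to 19.99 ± 3.58, P4ha1 from 31.6 ± 0.769 to 15.3 ± 0.806 and Pfkp from 26.7 ± 0.650 to 15.6 ± 0.376. Of 20 genes, 7 fell and none rose (8 and 0 adjusted over the list alone), with a median log2 fold change of -0.29 (camera adjusted p = 0.0048, and adjusted p = 0.107 with an estimated correlation). Oasl2 rose from 7.51 ± 0.454 to 20.2 ± 0.871 FPKM, Oas1a, which has close paralogs, from 11.8 ± 0.533 to 28.2 ± 3.07 and Irf7 from 19.2 ± 0.127 to 30.4 ± 2.78. Of 18 interferon-stimulated genes, 8 rose and 3, among them Mx1 and Ifit3, fell (8 and 3 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.013, and adjusted p = 0.20 with an estimated correlation). Mx1 fell from 1.27 ± 0.0780 to 0.514 ± 0.134 FPKM, while Ifit3 was not called without R 2 (limma adjusted p = 0.073). The genes that fell furthest under the naming rule were Tslp, a cytokine gene (193 ± 17.7 to 1.81 ± 0.724 FPKM, -6.43 ± 0.26), Thbs2 (14.6 ± 2.80 to 0.111 ± 0.0447), Cd34 (21.9 ± 1.22 to 0.851 ± 0.400), Stc1 (9.71 ± 0.542 to 0.144 ± 0.125), Inhbb (16.2 ± 1.98 to 0.605 ± 0.126) and Gas1 (75.1 ± 3.37 to 4.66 ± 1.05).

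In all, limma called 4937 of 15867 genes between RD7 and R, 2121 higher and 2816 lower (43.0% higher). With median-of-ratios scaling 2551 were higher and 2170 lower (54.0% higher), and with the length trend removed 2633 and 2384 (52.5% higher). With a minimum fold of 2, 1084 were higher and 750 lower, so which direction held more genes depended on the scaling and on the minimum fold. Groups did not overlap for 51.8% of genes, where chance gives 10% for a gene taken alone, with the same limit as above. The number higher was 1403 without R 2, and the number lower was 1800 without R 2, 1710 without R 3 and 1826 without RD7 2. Lists not called were Notch (Hey1, Nrarp, Dll1 and Jag1 fell, of 14, camera adjusted p = 0.058), sterol synthesis (4 fell, among them Sc5d and Sqle, of 20, 0.274) and mesenchymal markers (Dcn rose and Acta2, Col3a1, Pdgfrb, Col1a1 and Vim fell, of 10, 0.274). So were immediate-early and heat-shock genes (Hspb1, Atf3 and Jund rose and 6 fell, of 18, 0.464), fatty acid synthesis (Thrsp, Agpat2 and Scd1 rose and Elovl6 and Fads1 fell, of 16, 0.597) and the BMP and TGF-β response (Ccn2 and Id2 rose and Id4, Bmp2, Bmp4 and Id3 fell, of 16, 0.623). The calls of Jag1, Pdgfrb, Col1a1, Vim, Jund, Scd1 and Fads1 were lost without R 3. The calls of Id3 and some of these were lost without R 1, R 2, RD7 1, RD7 2 or RD7 3 (limma adjusted p up to 0.288). The fatty acid list's median (-0.13) and mean (0.09) differed in sign.

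**Figure D3:**
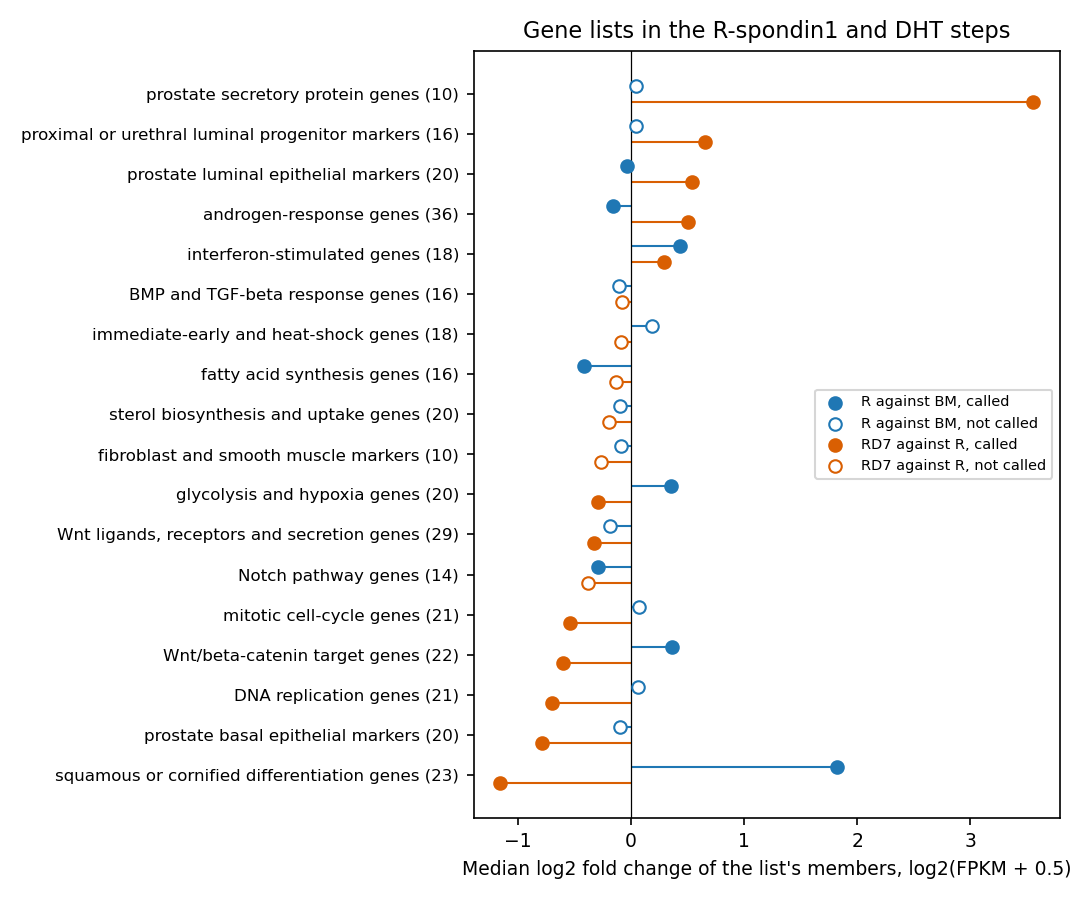
Median log2 fold change of each of the 18 gene lists tested, with the number of members tested in brackets, for R against BM and RD7 against R, where filled points mark lists that camera called with a preset correlation. The squamous list lies at 1.82 with R-spondin1 and at -1.15 with DHT, and the secretory list at 3.55 with DHT.

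R-spondin1 and DHT together were compared with BM to describe the sum of both steps. Secretory genes rose, with 7 of 10 higher and none lower (7 and 0 adjusted over the list alone) and a median log2 fold change of 3.45, or 4.03 with the members at 0 set to their bound (camera adjusted p = 7.1e-06, and adjusted p = 0.060 with an estimated correlation). Sbp rose from 2 reads over the BM libraries to 174 ± 15.1 FPKM, with a 95% counting interval of the ratio of 1778 to 53036. Vsig8 rose from 0.104 ± 0.0924 to 73.9 ± 9.72 FPKM and the antimicrobial peptide gene Defb1 from 2.18 ± 0.808 to 246 ± 30.7. Abo was listed at 0 in all 3 BM libraries and was at least 1304-fold higher than 3 reads over the BM group. Gsdmc2 fell from 113 ± 6.99 to 0.366 ± 0.0736 FPKM, Gsdmc3 from 96.4 ± 16.9 to 0.245 ± 0.117, Gsdmc4 from 24.2 ± 3.75 to 0.170 ± 0.0253 and Scara3 from 64.8 ± 16.1 to 1.18 ± 0.0622. Adh1, which fell with R-spondin1 and rose with DHT, stood at 37.6 ± 8.79 FPKM in BM and 44.7 ± 7.86 in RD7 and was not called (limma adjusted p = 0.295).

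Of 23 squamous genes, 12 were higher in RD7 than in BM, 11 of them among the 21 that rose with R-spondin1, and 1, Ivl, was lower (12 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0021, and adjusted p = 0.282 with an estimated correlation). Krt10 stood at 41.7 ± 14.6 FPKM in RD7 against 1.93 ± 0.480 in BM (log2 fold change 4.09 ± 0.23, limma adjusted p = 7.6e-07). Axin2 was higher in RD7 than in BM (2.39 ± 0.19, limma adjusted p = 8.6e-06), while Lgr5 (0.01 ± 0.11), Notum (-0.08 ± 0.19) and Nkd1 (-0.11 ± 0.12) were not called. Of 22 Wnt targets, Wif1, Lef1, Axin2, Bambi and Tnfrsf19 rose and 8 fell, the list was not called (camera adjusted p = 0.969), and its median (-0.09) and mean (0.03) differed in sign. Interferon-stimulated genes rose, with 12 of 18 higher and 1, Ifit2, lower (12 and 1 adjusted over the list alone), where Ifit2 was not called without BM 1, BM 2 or RD7 3 (limma adjusted p up to 0.074). The median was 1.30 (camera adjusted p = 4.4e-05, and adjusted p = 0.110 with an estimated correlation). Of 36 androgen-response genes, 20 rose and 12 fell (20 and 13 adjusted over the list alone), with a median of 0.44 (camera adjusted p = 0.0021, and adjusted p = 0.199 with an estimated correlation). Proximal markers rose, with 9 of 16 higher and 3, Clu, Ltf and Trpv6, lower (10 and 4 adjusted over the list alone) and a median of 0.63. For these, camera gave an adjusted p of 0.034, and an adjusted p of 0.390 with an estimated correlation, 0.175 with the length trend removed and 0.053 without RD7 2, in a range of 0.015 to 0.390.

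The replication, mitosis, basal, Notch and Wnt ligand lists fell from BM to RD7. Replication had 14 of 21 lower and none higher (14 and 0 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 9.4e-04, and adjusted p = 0.110 with an estimated correlation). Mitosis had 13 of 21 lower and none higher (15 and 0 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.0021, and adjusted p = 0.199 with an estimated correlation). Basal genes had 14 of 20 lower and 3, Dlk2, Aqp3 and Krt15, higher (14 and 3 adjusted over the list alone), with a median of -0.95 (camera adjusted p = 0.011, and adjusted p = 0.254 with an estimated correlation). Krt15 was not called with the length trend removed (limma adjusted p = 0.052). Notch genes had 9 of 14 lower and 1, Hes1, higher (9 and 1 adjusted over the list alone), a call lost without BM 1, BM 2, R 1, RD7 2 or RD7 3 or with the length trend removed (limma adjusted p up to 0.163). Their median was -0.80 (camera adjusted p = 0.0029, and adjusted p = 0.254 with an estimated correlation), and Hey1 fell from 26.7 ± 2.22 to 2.63 ± 0.121 FPKM. Wnt ligands and receptors had 13 of 29 lower and 2, Fzd9 and Wnt4, higher (13 and 2 adjusted over the list alone), with a median of -0.50 (camera adjusted p = 0.011, and adjusted p = 0.254 with an estimated correlation). Lists not called were sterol synthesis (Mvk and Fdps rose and 10 fell, of 20, camera adjusted p = 0.065), mesenchymal markers (Dcn rose and Vim, Acta2, Col3a1 and Pdgfrb fell, of 10, 0.088) and luminal genes (9 rose and Cd38, Krt8, Foxa1 and Krt18 fell, of 20, 0.116). So were fatty acid synthesis (Thrsp, Agpat2 and Elovl1 rose and 9 fell, of 16, 0.169), the BMP and TGF-β response (Tgfbi and Id2 rose and 6 fell, of 16, 0.220), glycolysis and hypoxia (Ankrd37, Pgk1 and Egln3 rose and 6 fell, of 20, 0.532) and immediate-early genes (Hspb1, Atf3, Zfp36, Dusp1 and Jund rose and 6 fell, of 18, 0.870). The calls of Fdps, Foxa1, Pgk1, Egln3, Jund and the Wnt target Tnfrsf19 were lost without BM 1, and at least 1 of them without each of the other 8 libraries (limma adjusted p up to 0.492). Col3a1 was not called with the length trend removed (limma adjusted p = 0.053).

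Among the fixed genes, Fkbp5 rose from 5.84 ± 1.22 FPKM in BM to 109 ± 16.3 in RD7, and Krt8 fell from 1173 ± 99.5 to 817 ± 108 (limma adjusted p = 0.012). Krt18 (-0.56 ± 0.17, limma adjusted p = 0.023) was not called without RD7 1 or RD7 3 (0.071 and 0.057). Mki67 (-0.82 ± 0.27, 0.031) was not called without BM 1, BM 2, RD7 1 or RD7 2 (up to 0.120) or with the length trend removed (0.134). Trp63 (-0.61 ± 0.22, 0.045) was not called without BM 1, BM 2, R 1, R 2, RD7 2 or RD7 3 (up to 0.158), with median-of-ratios scaling (0.068) or with the length trend removed (0.231). In Mki67 and Trp63 the libraries of the groups overlapped. Krt5 (limma adjusted p = 0.472) and Krt14 (0.994) were not called. Groups did not overlap for 52.4% of genes between RD7 and BM, where chance gives 10% for a gene taken alone, with the same limit. In all, limma called 7455 genes between RD7 and BM, 3425 higher and 4030 lower. Without RD7 2 these counts were 2220 and 2616. With median-of-ratios scaling 52.5% of calls were higher and with the length trend removed 51.5%, against 45.9%, and with a minimum fold of 2, 1368 were higher and 1209 lower.

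Genes called in both the R-spondin1 and DHT steps were counted by direction. The 364 genes that rose with R-spondin1 and fell with DHT included Calm4, Sprr2d, Lgr5 and Tslp, and the 329 that fell and then rose included Adh1, Upk3a, Prom1 and Spdef. Upk3a rose only from 1.57 ± 0.294 FPKM in R to 2.91 ± 0.761 in RD7 (limma adjusted p = 0.040), far below its 92.9 ± 26.7 in BM. Another 59 genes rose in both steps and 146 fell in both, among them Gsdmc2, Upk1a and Upk1b. If the calls of the steps were independent, 124, 120, 93.0 and 159 genes would fall in these classes. Simulations of unchanged groups gave 0 in each, but with no changed genes almost none are called, so this sets no level for the observed counts. Both steps use the same 3 R libraries with opposite sign, which alone gives opposite directions. The covariance of the log2 fold changes across genes was -0.073, against -0.022 in the simulations, while their correlation was smaller in size than in the simulations, -0.19 against -0.50. With 3 R libraries the shared part could not be split off. Without BM 3, 448 genes rose and then fell and 451 rose in both steps, so that the genes raised by R-spondin1 no longer fell more often than they rose with DHT, and 232 fell in both. Without R 1, R 2 or R 3 the class that rose in both held 28, 26 and 29 genes and the class that fell in both 74, 73 and 74, and the class that rose and then fell held 223 without R 1 and 234 without R 2.

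**Figure D4:**
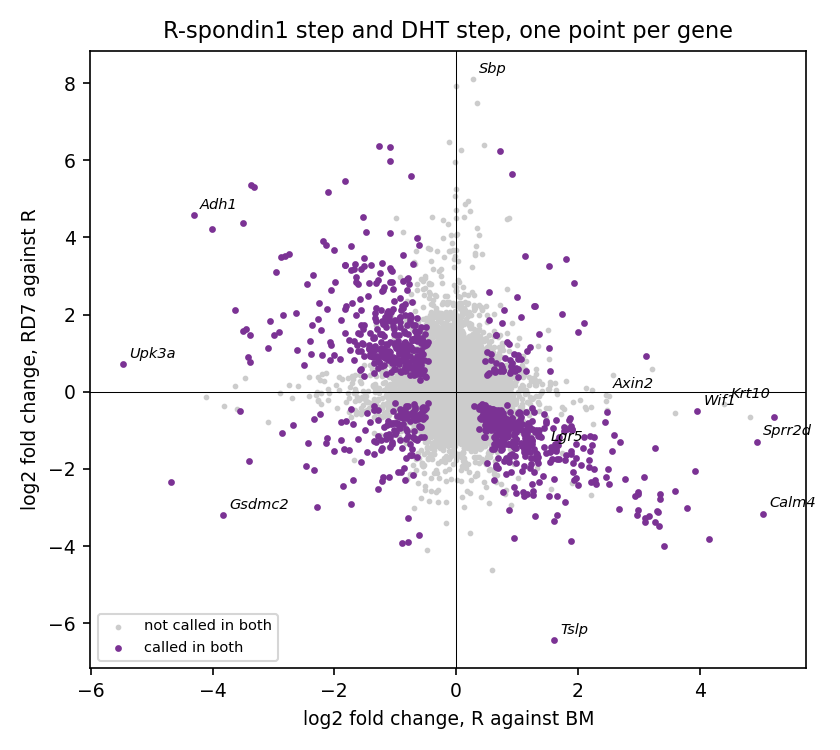
Log2 fold change on the log2(FPKM + 0.5) scale with R-spondin1 (horizontal) against that with DHT (vertical), with a point for each of 15867 genes and genes called in both steps in purple. The lower right part holds the 364 genes that rose and then fell, and the upper left the 329 that fell and then rose.

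Markers of other cell types stood low in most cases. The leukocyte marker Ptprc stood at 0.00151 ± 0.00261 FPKM in BM, 0.00114 ± 0.00198 in R and 0.00215 ± 0.00373 in RD7, and Tyrobp was listed at 0 in every library. Cd68, a lysosomal protein gene, stood at 1.21 ± 0.364, 2.64 ± 0.434 and 2.39 ± 0.647 FPKM, and Csf1r at 3.18 ± 0.321, 2.84 ± 0.206 and 2.29 ± 0.647. The endothelial marker Pecam1 stood at 0.122 ± 0.0490, 0.217 ± 0.0661 and 0.247 ± 0.0561 FPKM, the neuroendocrine marker Chga at 0.132 ± 0.103, 0.0385 ± 0.0345 and 0, and the seminal vesicle gene Svs5 at 0.0477 ± 0.0420, 0.0323 ± 0.0560 and 0.508 ± 0.282. Lyz2 was listed at 0 in BM and stood at 0.648 ± 0.00709 FPKM in R and 0.848 ± 0.511 in RD7. Both Cd68 and Lyz2 were called higher in RD7 than in BM, the call of Cd68 being lost without BM 1, BM 2, RD7 2 or RD7 3 or with the length trend removed (limma adjusted p up to 0.122), and both in R than in BM. These lists had 4 (immune), 3 (endothelial), 1 (neuroendocrine) and 1 (seminal vesicle) members tested and were not tested as lists. Of the mesenchymal markers, Col1a1 stood at 0.128 ± 0.153, 0.240 ± 0.0597 and 0.0197 ± 0.0275 FPKM and Vim fell from 1.37 ± 0.139 in BM to 0.236 ± 0.0554 in R. Acta2, smooth muscle actin, fell from 12.4 ± 3.43 to 3.69 ± 0.984 and then to 1.29 ± 0.285 in RD7. Dcn, a matrix proteoglycan gene, rose from 4.79 ± 1.27 to 21.9 ± 2.71 and then to 76.6 ± 14.1. The genes in this paragraph were chosen from the fixed lists after their values were seen.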

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

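Pseudocounts of 0.1 and 1 FPKM, limma-voom, the removal of the length trend and median-of-ratios scaling for the list tests were tests chosen only after the data had been seen, and the other alternatives were planned. The planned count-based edgeR and DESeq2 Wald tests were not run. The deposited values are FPKM, and the reads read back from them were tested with limma-voom alone. Of 185 called values of named genes, none changed direction in any alternative run. The log2 fold change is the same by design with another filter, in the fit of 6 libraries and with the block. The same holds when a library outside the comparison is left out, so the direction could not change in these runs. The call was lost for 19 when each library was left out in turn, 12 with the replicate number as a block, 10 with the length trend removed, 9 with no filter, 9 in a fit of 6 libraries, 3 with median-of-ratios scaling, 2 with limma-voom, and 0 with either pseudocount or the stricter filter. Calls lost with the block were Krt15, Snai2, P4ha1, Egln3 and Dgat2 in R against BM and Krt18 and Trp63 in RD7 against R. In RD7 against BM they were Mki67, Krt16, Egln3, Krt18 and Trp63. None of the 30 lists called by camera changed direction in a setting run for lists. Of 24 list results not called, 4 did, 3 of them with fry (basal genes in R against BM, and Wnt targets and immediate-early genes in RD7 against BM). Medians of some lists not called changed sign as well, and that of the mesenchymal list in R against BM went from -0.09 to 0.10 with the length trend removed. Which direction held more of the called genes turned in RD7 against R (43.0% higher, and 54.0% with median-of-ratios scaling or 52.5% with the length trend removed), in RD7 against BM (45.9%, 52.5% and 51.5%) and in R against BM without BM 3 (43.7% and 61.4%). All 30 list calls held with median-of-ratios scaling, fry and the block, and fry called 16 further list results that camera did not. Camera compares list members with the other genes, and the scaling shifts both nearly alike, so it could hardly change these calls. Fry asks whether members change at all, not whether they change more than other genes, so its calls do not bear on those of camera. With an estimated correlation, 28 of the 30 calls were lost. Deviations from group means of libraries with the same replicate number correlated across genes at -0.52 to 0.27. Libraries with different numbers could correlate more strongly, as BM 3 and R 1 did at 0.58. These values gave no sign of pairing but cannot show whether equal numbers share an origin. With genes simulated independently, the test found between 35.4% and 44.0% of 2-fold changes, so that smaller changes were often not detectable at this depth and number of libraries.

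With a minimum fold of 2, fewer genes passed by construction: 266 higher and 424 lower in R against BM, 1084 and 750 in RD7 against R, and 1368 and 1209 in RD7 against BM. More genes were then higher than lower in both comparisons of RD7, against fewer with no minimum fold. With the replicate block, which takes up residual degrees of freedom, 461 genes were higher in R than in BM, 32 rose in both steps and 97 fell in both. With no filter 90 fell in both, and the cause was not tested.

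Camera with an estimated correlation allows for correlated members, and the adjusted p of these lists passed 0.05. In R against BM it was 0.220 for Wnt targets, 0.243 for androgen-response genes, 0.322 for luminal genes, 0.059 for squamous genes, 0.243 for fatty acid synthesis, 0.322 for Notch, 0.104 for glycolysis and hypoxia and 0.147 for interferon. In RD7 against R it was 0.193 for Wnt targets, 0.320 for Wnt ligands and receptors, 0.067 for androgen-response genes, 0.117 for basal genes, 0.107 for luminal genes, 0.323 for proximal markers, 0.108 for squamous genes, 0.107 for mitosis, 0.107 for glycolysis and hypoxia and 0.20 for interferon. In RD7 against BM it was 0.254 for Wnt ligands and receptors, 0.199 for androgen-response genes, 0.254 for basal genes, 0.390 for proximal markers, 0.060 for secretory genes, 0.282 for squamous genes, 0.199 for mitosis, 0.110 for replication, 0.254 for Notch and 0.110 for interferon. With the length trend removed, camera gave 0.061 for androgen-response genes in R against BM, 0.0504 for Wnt ligands and receptors in RD7 against R and 0.175 for proximal markers in RD7 against BM, and the cause was not tested.

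With each library left out in turn, 368 (R 1) to 2089 (BM 3) genes were higher and 559 (R 2) to 1313 (BM 3) lower in R against BM, with 458 higher without BM 1, 381 higher without R 2 and 562 lower without R 1. In RD7 against R, 1403 (R 2) to 2631 (BM 3) were higher and 1710 (R 3) to 3108 (BM 3) lower, with 1800 lower without R 2 and 1826 without RD7 2. In RD7 against BM, 2220 to 4076 were higher and 2616 to 4443 lower, both lowest without RD7 2 and highest without BM 3. The luminal list in R against BM had a camera adjusted p of 0.0043 to 0.141, the highest without BM 3 and 0.085 without R 3. For the proximal list in RD7 against BM it was 0.015 to 0.053, the highest without RD7 2. From 26 (R 2) to 451 (BM 3) genes rose in both steps, with 28 without R 1 and 29 without R 3, and from 73 (R 2) to 232 (BM 3) fell in both, with 74 without R 1 and 74 without R 3. From 223 (R 1) to 448 (BM 3) rose and then fell, with 234 without R 2. Each highest count of genes came without BM 3, which fewer libraries alone do not explain. In RD7 against R the BM libraries enter the fit only through the estimated spread of each gene. The higher counts there without BM 3 therefore came from that estimate. A fit of the R and RD7 libraries alone called 2737 higher and 3336 lower. For the other changes, apart from there being fewer libraries, the cause was not tested.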

Other observations

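The tests of other splits of the libraries were planned, and the tests of gene length, ribosomal-protein genes, labels, cell share and urothelial cells, like the gene families described here, were chosen only after the results were seen. Genes of the following families were called, but the families were not tested as sets, and Ccn2 and Aldh1a3 also belong to fixed lists. The kallikrein genes Klk6 to Klk10, Klk13 and Klk14, secreted serine proteases of which some act in the cornified layer of skin, rose with R-spondin1 and fell with DHT by limma. The kallikrein gene Klk1b24 did neither, standing at 0.0584 ± 0.101 FPKM in BM, 0 in R and 0.866 ± 0.0778 in RD7. Klk10 went from 0.715 ± 0.0573 FPKM in BM to 9.96 ± 0.964 in R and 0.528 ± 0.248 in RD7, and Klk13 from 0.217 ± 0.120 to 6.32 ± 0.161 and 0.159 ± 0.0594 (SD, n = 3). The rise of Klk8, from 1.65 ± 0.579 to 3.52 ± 0.635 FPKM, was not called without BM 2, R 1 or R 2 or with the length trend removed (limma adjusted p up to 0.125). Of 10 target genes of the YAP and TAZ coactivators, 5 fell with R-spondin1, Ccn2 (158 ± 18.3 to 14.4 ± 0.880 FPKM), Ankrd1 (5.06 ± 0.577 to 0.640 ± 0.219), Thbs1 (169 ± 55.7 to 50.6 ± 11.3), Axl and Lats2. Axl was not called without BM 1, BM 2, R 1, R 2, R 3 or RD7 2 (limma adjusted p up to 0.173), nor Lats2 without BM 1, BM 2, R 1, R 2 or RD7 3 (up to 0.166). Reads of close paralogs in the kallikrein family cannot be assigned with certainty.

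With DHT, 9 of 12 acute-phase and innate defence genes rose and 1, C3, fell. Lbp, which encodes a lipopolysaccharide-binding protein, rose from 20.8 ± 1.14 FPKM in R to 298 ± 17.7 in RD7, Lcn2, an iron-siderophore binding protein gene, from 84.6 ± 16.4 to 587 ± 84.3, and Serpina3n from 0.0325 ± 0.0336 to 6.24 ± 0.885. The serum amyloid genes Saa3 and Saa1, close paralogs, rose from 1.94 ± 0.749 to 16.7 ± 5.45 and from 0.155 ± 0.0918 to 8.42 ± 1.42, while the complement gene C3 fell from 32.9 ± 6.99 to 14.4 ± 3.57. Of the Aldh1a family of aldehyde dehydrogenase genes, Aldh1a1 rose from 15.6 ± 0.764 to 184 ± 25.3 and its paralog Aldh1a7 from 5.83 ± 0.388 to 74.4 ± 6.37, and Aldh1a3 fell from 91.8 ± 4.87 to 37.2 ± 4.15. Reads of Aldh1a1 and Aldh1a7 cannot be assigned with certainty either.

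Shorter genes were higher in R than in BM, and a difference in medium or a technical difference could give this trend. Among libraries of BM alone, BM 3 minus the others had a Spearman correlation with length of -0.45 across genes, larger in size than that between R and BM (-0.33), so length-dependent recovery that differs between libraries has the values it needs and stays open. Without the 128 ribosomal-protein genes, of 15867 tested, the correlation between R and BM stayed at -0.33. So few genes can hardly move a rank correlation over all genes, so this shows only that the other genes carry the trend. The squamous list kept a camera adjusted p of 1.6e-27 with the trend removed (range over the alternatives 1.6e-27 to 0.059), which argues against length as the whole cause of its rise. BM 3 lay nearer to R, but over Axin2, Lgr5, Notum and Nkd1 it lay a median of -1.06% of the way from the other BM libraries to R, against a library with R-spondin1 under a BM label. An effect of medium on length-dependent recovery was not tested.

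Targets that R-spondin1 had raised parted with DHT, and fewer R-spondin1-responding cells in RD7 could be a technical or cellular source. A lower share of such cells would leave each target a like share of its rise, but for 8 of the 9 targets besides Axin2 the highest share kept in any RD7 library lay below the lowest of Axin2 (79.9%). Lgr5 kept -1.06% to 2.20% and Wif1 62.3% to 75.6%, while Lef1, the exception, stood at 234% to 354%. These shares take the mean of R as fixed, although Axin2 ran from 3.36 to 5.59 FPKM over the R libraries. The count of 8 leaves out that spread, which matters most for Wif1 and Tnfrsf19 (26.9% to 71.3%), the nearest below Axin2. With the length trend removed, the log2 fold change of Lgr5 minus that of Axin2 was -1.35, against -1.36 before, which argues against gene length. No biological explanation was tested, and the source of the split stays open.

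Of 5 uroplakin genes tested, 3 fell from BM to R, Upk1a from 67.2 ± 14.7 to 9.89 ± 1.28 FPKM, Upk1b from 109 ± 19.3 to 24.6 ± 2.30 and Upk3a from 92.9 ± 26.7 to 1.57 ± 0.294, while Upk2 (0.930 ± 0.402 and 0.637 ± 0.195) and Upk3bl (1.91 ± 0.321 and 2.83 ± 0.610) were not called. Superficial urothelial cells among the sorted basal cells might bring the 3 that fell, but Upk2, abundant in such cells, reached at most 1.12% of the Upk3a level in any BM library, and Krt20, their keratin, rose from 0.756 ± 0.0559 in BM to 5.39 ± 0.703 in R. The low Upk2 and Krt20 levels in BM argue against superficial cells that express both, which the sort for basal cells should also remove. No reference profile of urothelium was compared, and other urothelial cells, or cells that changed in culture, were not tested for. With the length trend removed, the highest limma adjusted p of Upk1a, Upk1b and Upk3a was 2.3e-06, against gene length. Why these 3 genes were high in BM stays open.

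Each split of 6 libraries into 3 and 3 is 1 of 10, too few for a share under 0.05. In R against BM the real split called 1591 genes and 8 lists, and the highest of the other splits 0 genes and 4 lists. In RD7 against R these were 4937 genes and 12 lists, against 0 and 6, and in RD7 against BM 7455 and 10, against 0 and 6. In each of these 6 counts 1 split, the real one, gave as many. Of 100 drawn assignments of the 9 libraries to 3 groups, 2, the real one among them, gave at least the 693 genes called in opposite directions in the R-spondin1 and DHT steps, a share under 0.05. As the other splits of 6 libraries called 0 genes, this count depends on the separation of the groups, so it excludes only a random assignment of the libraries to the groups and says nothing about whether directions were opposite more often than the shared R libraries give. The other gave 2610, several times as many, and it kept the 3 RD7 libraries together as the middle group, so that this count points to a structure of the samples.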
